A study of Mus musculus with 14 samples.

How the data were processed

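Polyadenylated RNA was measured in 14 mouse nucleus accumbens samples, 7 injected with AAV-Cre and 7 with AAV-GFP. Per the labels' protocols, RNA was extracted with Trizol and made into libraries with an Illumina TruSeq mRNA kit, with 1 barcoded library per mouse. The submitters' processing notes name TopHat2 2.0.9 and Bowtie2 2.1.0 and the builds GRCm38 and mm10. The counting tool, the annotation, the normalization, the filter on low genes and the model are not given in the sources used here.

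The data are 1 table of the authors' own comparison, with 13130 genes. Per the file headers, the deposited log2 values are a log2 fold change and a mean log2 level per gene, and the column names are those that limma writes. Per the file headers, the deposited score columns are a moderated t and a log-odds value, of which t was used. The deposited p-value columns, per the file headers, are an unadjusted and an adjusted p-value. The adjusted column equals the Benjamini-Hochberg adjustment of the 13130 p-values to within 1e-06. The p-values follow from t with 15.1 degrees of freedom in every row. A model with 12 residual and 3.15 prior degrees of freedom would give that, as would other combinations. The linear mean levels sum to 991364, close to the total that log2 CPM values would give, and a mean level of 1 CPM is used here in that sense. The direction, AAV-Cre minus AAV-GFP, is taken from the name of the deposited table and could not be tested on library values. Depth per library is unknown, so no interval or floor that needs counts is given.

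Standard errors were derived as the log2 fold change divided by t, and 95% limits from them with the same degrees of freedom. Stable gene IDs matched the reference names for 13063 of the 13130 genes, and coordinates and exonic lengths came from GENCODE M21 on GRCm38. The exonic length of a gene joins the exons of all its annotated transcripts. Where 2 rows shared a symbol, the stable ID decided.

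The planned tests on library values could not be run, and the fallback fixed before the data were examined was used: a description of the authors' fold changes and p-values, and limma's camera test on their t. Camera asks whether a list's t-values differ from those of all other genes. It was run two-sided with a preset correlation of 0.01, over the 39 of 41 lists with at least 5 measured members, with Benjamini-Hochberg adjustment. The lists were fixed before the data were examined and cover cell types of the region and its neighbours, neuronal function, immune and glial reaction, stress and DNA methylation. Counts adjusted over the list alone use the authors' p-values of its members. Random lists matched on mean level were drawn 10000 times, as were bootstrap medians. The bootstrap drew the member genes of a list with replacement, so its intervals describe spread among genes and not between mice.

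The rule for named genes was also fixed before the data were examined. It takes Tet1, Tet2 and Tet3, then up to 12 genes per direction past an adjusted p of 0.05 with a mean of at least 1 CPM and no predicted or clone name. Where fewer pass, each direction is filled to 6 genes by smallest p. In each described list up to 4 members of smallest p are named.

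The list test was tested on simulated statistics for 13130 genes and 39 lists. With no effect and independent genes it called 0.02 lists on average, against 0.73 with a correlation of 0.05 inside lists and 2.47 with 0.1. A planted list of 20 genes shifted by 1 in t was found in 77% of 100 simulations, and one shifted by 0.5 in 5%. When 200 random genes were changed by a log2 value of 0.5, 1 or 2, 71.3%, 92.9% and 98.8% passed an adjusted p of 0.05, given those genes' own standard errors. The draws were independent, and the median standard error over all genes was 0.079. These shares therefore do not apply to the 67 interferon, MHC and leukocyte genes, whose median standard error was 0.273.

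Alternatives to the gene counts were an adjusted threshold of 0.1 and a mean of at least 1 CPM. Alternatives to the list test, chosen after seeing the data, were correlations of 0.05 and 0.1, ranks of t, the fold change as statistic, a mean of at least 1 CPM, shared members left out, and the trend of t with exonic length removed (lowess, fraction 0.3). Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.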

Results

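Messenger RNA of the nucleus accumbens, a ventral striatal region of the brain's reward circuit, was sequenced from 14 C57BL/6 mice whose Tet1 alleles carry loxP sites. Tet1 encodes an enzyme that oxidises 5-methylcytosine in DNA. In 7 mice an adeno-associated virus (AAV) carrying Cre, the recombinase that deletes DNA between loxP sites, was injected into the region. The 7 control mice received the same type of virus carrying green fluorescent protein (GFP). RNA was taken 4 weeks after injection and each mouse was sequenced as its own library. The series title places the comparison in a study of Tet1 and responses to stress. The values used here are the authors' deposited comparison of AAV-Cre with AAV-GFP for 13130 genes. They hold no value per library, so the depth of each library is unknown, and levels, SDs and outlying mice cannot be given.

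Tet1 transcript was 8.43% lower in AAV-Cre than in AAV-GFP in the authors' deposited table, a log2 fold change of -0.13 with a standard error of 0.11. Its 95% limits, derived from that table, ran from a log2 value of -0.36 (-21.9%) to 0.10 (7.32%), and the adjusted p was 0.921 (unadjusted p = 0.255). The gene, ENSMUSG00000047146.11, lies on the minus strand of chromosome 10 from 62804570 to 62908996 (GRCm38). The related dioxygenase genes Tet2 and Tet3 had log2 fold changes of -0.06 and -0.02 in the authors' deposited table, with adjusted p of 0.952 and 0.982. The exons between the loxP sites are not given in the labels, and cells without virus keep the gene, so this value over the whole transcript does not measure recombination.

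No single gene passed the adjusted threshold of 0.05 between AAV-Cre and AAV-GFP, and the smallest adjusted p in the authors' deposited table was 0.695. An unadjusted p under 0.05 was listed for 676 genes, 606 higher and 70 lower in AAV-Cre, where chance alone gives 656.5 in both directions together. Ifi47, an interferon-inducible GTPase gene, had a log2 fold change of 1.70 ± 0.36 (standard error) in the authors' deposited table. Casp1, which encodes the inflammasome protease, stood at 1.001 ± 0.23 there, the guanylate-binding protein gene Gbp5 at 0.94 ± 0.22 and the peptide transporter gene Tap2 at 0.72 ± 0.16. Trim47 (0.43 ± 0.09) and the X-linked deubiquitinase gene Usp27x (0.27 ± 0.06) completed the 6 genes named as higher from the authors' deposited table.

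On the lower side, the collagen gene Col19a1 had a log2 fold change of -0.66 ± 0.20 (standard error) in the authors' deposited table, and the cell adhesion gene Clmp -0.53 ± 0.20. The transferrin receptor gene Tfr2 (-0.39 ± 0.12), the fatty acyl-CoA reductase gene Far2 (-0.25 ± 0.09), Fam98a (-0.18 ± 0.06) and Fgf11 (-0.17 ± 0.05) were the other 4 in the authors' deposited table. None of these 12 genes passed: adjusted p was 0.695 for each of the 6 higher ones and between 0.778 and 0.919 for the lower ones.

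Interferon response genes rose as a list in AAV-Cre. All 32 measured members were higher, with a median log2 fold change of 0.87, and 28 passed when adjusted over the list alone, against 0 when adjusted over all genes. The list stood above the other genes at an adjusted p of 4.07e-40 (limma's camera test on the authors' statistic). The list members of smallest p in the authors' deposited table were the GTPase gene Iigp1 (log2 fold change 1.79 ± 0.42, standard error), the T cell-attracting chemokine gene Cxcl9 (3.89 ± 0.94), Gbp7 (0.77 ± 0.19) and Gbp2 (1.53 ± 0.39).

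Antigen presentation genes rose with them. For MHC class I and the machinery that loads it with peptide, 21 of 22 measured genes were higher, the median log2 fold change was 0.76, and 18 passed when adjusted over the list alone (list adjusted p = 7.45e-25). Besides Tap2, the members of smallest p in the authors' deposited table were the peptide-trimming protease gene Erap1 (0.38 ± 0.10), Tap1 (1.28 ± 0.33) and the heavy chain gene H2-K1 (1.33 ± 0.36). The 7 measured MHC class II genes had a median log2 fold change of 2.40 and a mean of 1.65. All 7 passed when adjusted over the list alone (list adjusted p = 2.03e-13 in the camera test). The rise was uneven: the bootstrap interval of the median, over genes, was 0.53 to 2.53, and members other than those named next stood lower. H2-Eb1, H2-Ab1, H2-Aa and the invariant chain gene Cd74 stood between 2.40 and 2.53 in the authors' deposited table, 5.30 to 5.79 times the AAV-GFP level, with standard errors of 0.56 to 0.61.

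**Figure D1:**
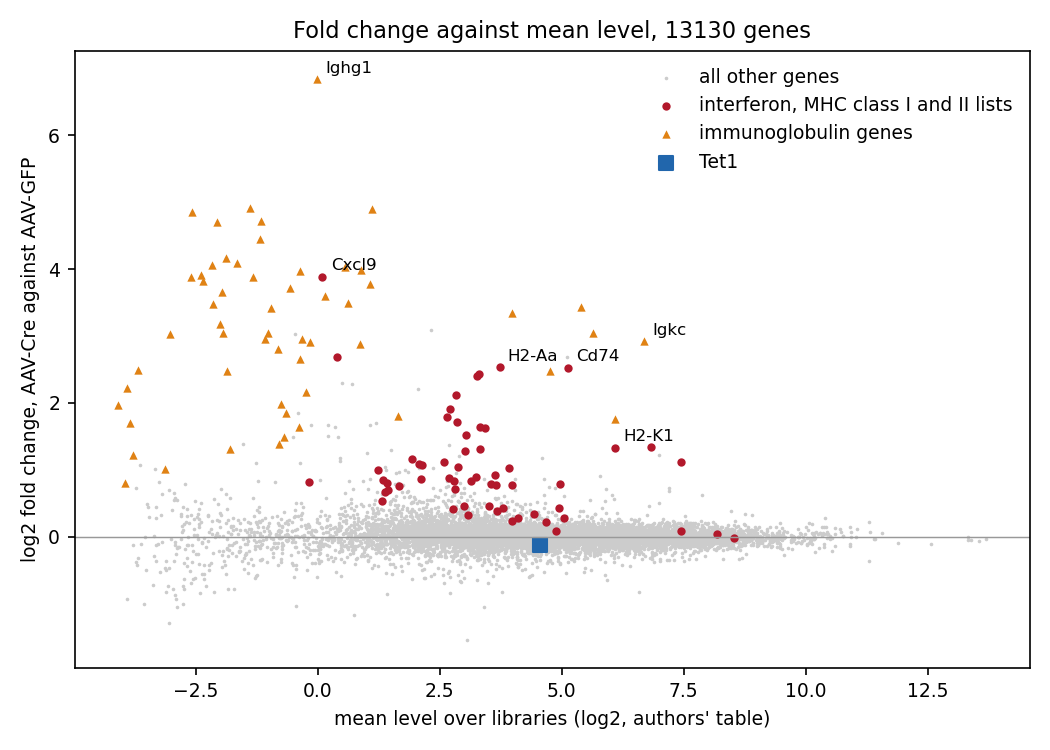
Each point is 1 of the 13130 genes, with its mean level over libraries on the x axis (log2) and its log2 fold change of AAV-Cre against AAV-GFP on the y axis, both from the authors' deposited table. Interferon and MHC genes (red circles) and immunoglobulin genes (orange triangles) lie mostly above 0, while Tet1 (blue square) lies at -0.13.

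Lists of glial reaction and of immune cells also rose in AAV-Cre. Activated microglia genes had a median log2 fold change of 0.64 over 21 measured members (13 passed adjusted over the list alone; list adjusted p = 1.84e-19), and the 4 members of smallest p were the same MHC class II genes. Microglia markers had a median of 0.35 over 22 members (list adjusted p = 1.82e-08). There 10 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. The cathepsin gene Ctss (0.72 ± 0.25), C1qa (0.72 ± 0.25), Aif1 (0.50 ± 0.18) and C1qc (0.53 ± 0.20) came first among them in the authors' deposited table. Reactive astrocyte genes had a median of 0.81 over 16 members (7 passed adjusted over the list alone; list adjusted p = 1.11e-11). Gbp2, the complement gene C3 (3.09 ± 0.85), H2-D1 (1.34 ± 0.37) and the intermediate filament gene Vim (0.91 ± 0.26) led them in the authors' deposited table. The general astrocyte markers did not pass (median 0.02, adjusted p = 0.831). Among these, Slc1a3 (0.20 ± 0.08), Gfap (0.69 ± 0.34), Mlc1 (0.17 ± 0.08) and Sox9 (0.19 ± 0.12) had the smallest p in the authors' deposited table.

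Chemokines, cytokines and their receptors were higher in all 28 measured members, out of 54 in the list. Their median log2 fold change was 0.25 (7 passed adjusted over the list alone, list adjusted p = 9.77e-12 in the camera test). Cxcl9, Cxcl10 (2.69 ± 0.79), Cxcl16 (0.96 ± 0.31) and Ccl5 (2.28 ± 0.75) came first in the authors' deposited table. Lymphocyte and other blood leukocyte genes had a median of 1.53 over the 8 of 29 members that the table holds (6 passed adjusted over the list alone; list adjusted p = 1.20e-06). The T cell receptor gene Trac (1.39 ± 0.40), Ccl5, the immunoglobulin light chain gene Igkc (2.92 ± 1.03) and the T cell kinase gene Lck (0.51 ± 0.21) led in the authors' deposited table. Genes of red blood cells did not share this shift: their 5 measured members had a median of -0.02 (adjusted p = 0.547). The globin genes Hbb-bs (-0.05 ± 0.42), Hbb-bt (-0.05 ± 0.44) and Hba-a1 (-0.02 ± 0.41) and the haem synthesis gene Alas2 (0.03 ± 0.41) lay near 0 in the authors' deposited table. Complement genes had a median of 0.53 over 13 members (5 passed adjusted over the list alone; list adjusted p = 2.62e-06), with Serping1 at 0.84 ± 0.25 and C4b at 1.23 ± 0.45 in the authors' deposited table beside C3 and C1qa. Of the 13, 7 belong to other lists too, and without shared members the complement call ended (adjusted p = 0.372).

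Ribosomal protein genes were higher in AAV-Cre in all 37 measured members, by a small and even amount. Their median log2 fold change was 0.16, 3 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (list adjusted p = 4.35e-12). Rpl10 (0.19 ± 0.09), Rpl41 (0.20 ± 0.09), Rpl6 (0.15 ± 0.07) and Rpl7 (0.15 ± 0.07) came first in the authors' deposited table, and the call ended with the fold change in place of t as the statistic (adjusted p = 0.0746). Endothelial markers were higher in all 18 members, with a median of 0.18 and 0 past the threshold adjusted over the list alone (list adjusted p = 1.72e-06). This call, led by Eng (0.30 ± 0.11), Cldn5 (0.29 ± 0.12), Cdh5 (0.27 ± 0.12) and Esam (0.20 ± 0.10) in the authors' deposited table, also ended with the fold change as statistic (adjusted p = 0.1005). Choroid plexus and ependymal markers had a median of 0.37 over 7 members, 0 of which passed adjusted over the list alone (list adjusted p = 0.0261; 0.0536 with the correlation preset at 0.05). Rarres2 (0.64 ± 0.27), the cilia genes Foxj1 (0.53 ± 0.25) and Rsph1 (0.37 ± 0.19) and Dynlrb2 (0.83 ± 0.46) led them in the authors' deposited table.

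**Figure D2:**
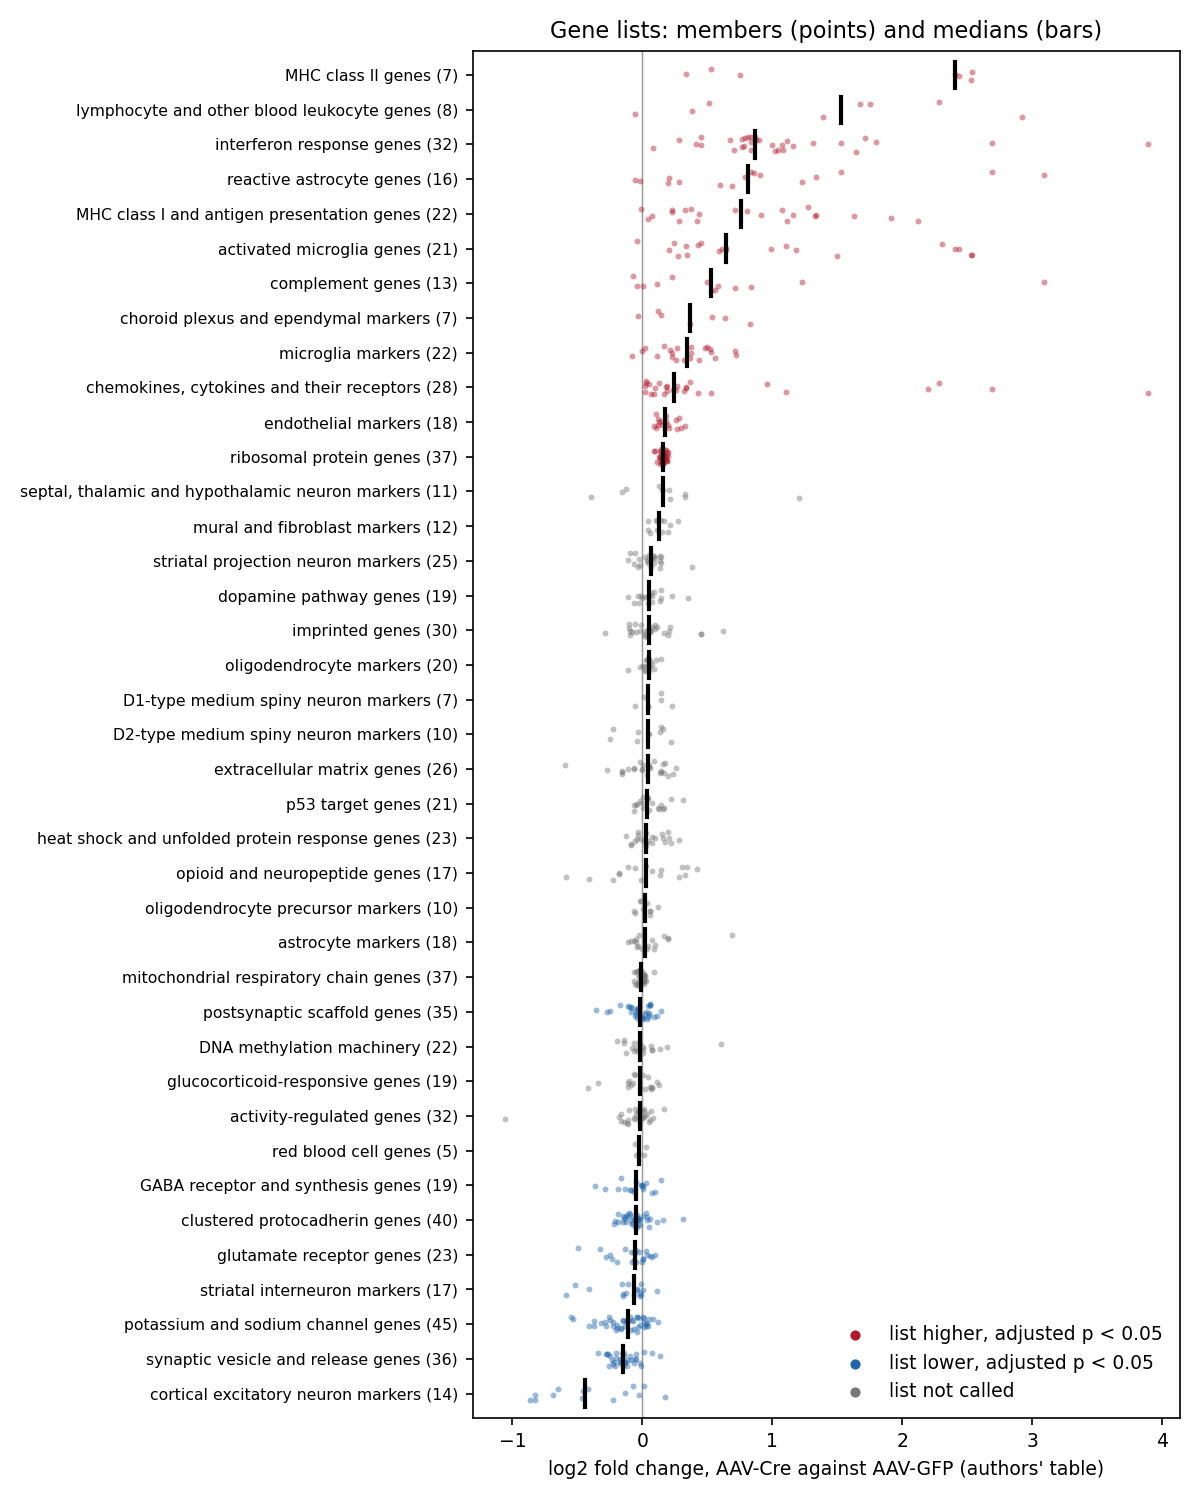
Log2 fold changes of AAV-Cre against AAV-GFP, from the authors' deposited table, for the measured members (points) of each of 39 gene lists, with the list median as a black bar and the number of members in brackets. The 12 lists in red and the 8 in blue stood above or below the other genes at an adjusted p under 0.05, from a median of 2.40 (MHC class II) to -0.44 (cortical excitatory neuron markers).

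Genes of synaptic release and of neuronal excitability stood lower in AAV-Cre than other genes. Synaptic vesicle and release genes were lower in 33 of 36 members, with a median log2 fold change of -0.15 (list adjusted p = 1.12e-09). Their members of smallest p in the authors' deposited table were the calcium sensor genes Syt7 (-0.14 ± 0.06) and Syt1 (-0.23 ± 0.12), Rims1 (-0.28 ± 0.14) and Synj1 (-0.17 ± 0.09). Potassium and sodium channel genes were lower in 34 of 45 members, with a median of -0.11 (list adjusted p = 5.77e-08). Scn8a (-0.20 ± 0.08), Kcna2 (-0.53 ± 0.23), Scn1a (-0.37 ± 0.17) and Kcnb2 (-0.26 ± 0.13) came first in the authors' deposited table. In both lists, 0 members passed adjusted over the list alone.

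Another 6 lists were called lower, each with 0 members past the threshold adjusted over the list alone. Markers of cortical excitatory neurons, cells that neighbour the region but do not belong to it, were lower in 12 of 14 members, with a median log2 fold change of -0.44 (list adjusted p = 0.00573; 0.0918 with the correlation preset at 0.1). Nptx1 (-0.65 ± 0.45), Fezf2 (-0.42 ± 0.32), Rorb (-0.13 ± 0.12) and Lamp5 (0.18 ± 0.16) had the smallest p in the authors' deposited table. The median standard error of these cortical genes was 0.386, or 4.23 times that of genes at the same level.

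**Figure D3:**
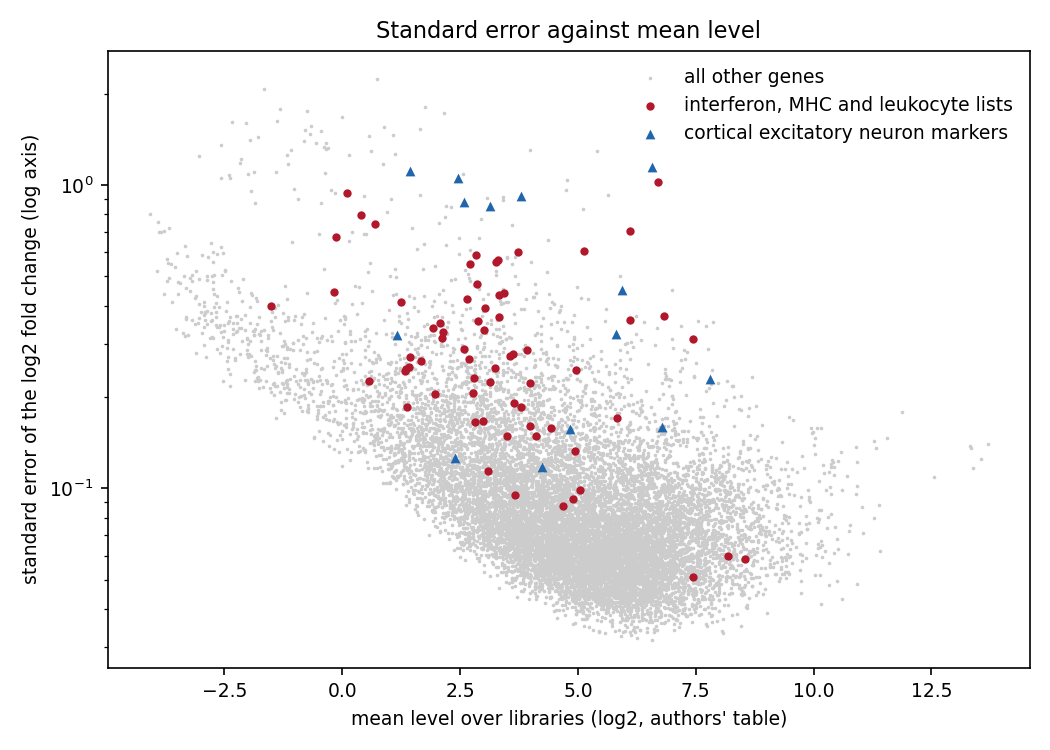
Standard error of the log2 fold change (y axis, log scale) against mean level over libraries (x axis, log2) for 13130 genes, derived from the authors' deposited table. Interferon, MHC and leukocyte genes (red circles, median 0.273) and cortical excitatory neuron markers (blue triangles, median 0.386) lie mostly above the other genes of their level.

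Clustered protocadherin genes, some of which share exons so that their reads may be hard to assign, had a median of -0.05 (list adjusted p = 0.00160, and 0.152 with the correlation preset at 0.1). Pcdhgb1 (-0.22 ± 0.12), Pcdhb12 (0.32 ± 0.18), PCDHA9 (-0.19 ± 0.12) and PCDHGB6 (0.11 ± 0.08) came first in the authors' deposited table. Glutamate receptor genes had a median of -0.06 (list adjusted p = 0.00406; 0.124 with the correlation preset at 0.1), led by Gria3 (-0.20 ± 0.08) and Grin2c (-0.23 ± 0.09) in the authors' deposited table.

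Striatal interneuron markers had a median log2 fold change of -0.06 over 17 members (list adjusted p = 0.0257; 0.0904 with the correlation preset at 0.05), with Nos1 at -0.15 ± 0.13 and Pvalb at -0.52 ± 0.54 in the authors' deposited table. For postsynaptic scaffold genes 15 of 35 members were higher and the median of -0.02 lay within the 95% range of level-matched lists (-0.03 to 0.03), although the list was called lower (adjusted p = 0.0286; 0.154 with the correlation preset at 0.05). Among them Cacng2 (-0.17 ± 0.09) and Dlgap1 (-0.27 ± 0.15) had the smallest p in the authors' deposited table. GABA receptor and synthesis genes had a median of -0.05 (list adjusted p = 0.0377; 0.134 with the correlation preset at 0.05), with Gabrb2 (-0.29 ± 0.20) among the members of smallest p in the authors' deposited table.

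Markers of the principal neurons of the region were not called. Striatal projection neuron markers had a median log2 fold change of 0.07 (adjusted p = 0.535), with Crym at 0.38 ± 0.18 and Adora2a at 0.14 ± 0.10 in the authors' deposited table. D1-type medium spiny neuron markers had a median of 0.05 (adjusted p = 0.499) and D2-type markers 0.05 (adjusted p = 0.967), with Isl1 at 0.23 ± 0.12 and Sp9 at 0.16 ± 0.10 in the authors' deposited table. Dopamine pathway genes (median 0.05, adjusted p = 0.496) and opioid and neuropeptide genes (0.03, adjusted p = 0.499) did not pass, nor did septal, thalamic and hypothalamic neuron markers (0.16, adjusted p = 0.197). Activity-regulated genes had a median of -0.02 (adjusted p = 0.0537), and glucocorticoid-responsive genes, which stress hormones control, also had -0.02 (adjusted p = 0.127). Among the latter Hif3a stood at -0.34 ± 0.14 in the authors' deposited table. The DNA methylation machinery, which includes Tet1 to Tet3, had a median of -0.02 and a mean of 0.01 over 22 members (adjusted p = 0.272).

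Of the other lists, oligodendrocyte markers (median 0.05, adjusted p = 0.988), oligodendrocyte precursor markers (0.02, adjusted p = 0.707) and extracellular matrix genes (0.04, adjusted p = 0.870) did not pass. Neither did mural and fibroblast markers (0.13, adjusted p = 0.0537), imprinted genes (0.05, adjusted p = 0.547), p53 targets (0.04, adjusted p = 0.165) or heat shock and unfolded protein response genes (0.03, adjusted p = 0.195). Respiratory chain genes had a median of -0.01 (adjusted p = 0.0537). For oligodendrocyte, oligodendrocyte precursor and neuropeptide lists the median was above 0 while the test placed the list below the other genes, whose mean t was 0.302. The camera test and the level-matched range differed for 8 lists that were not called. Of these, 6 had a median above the 95% range of level-matched lists: striatal projection neuron (-0.04 to 0.03), dopamine pathway (-0.041 to 0.046), septal, thalamic and hypothalamic (-0.05 to 0.11), mural and fibroblast (-0.04 to 0.10), imprinted (-0.023 to 0.043) and, by less than 0.001, oligodendrocyte genes. The other 2, activity-regulated genes (-0.01 to 0.06) and, by less than 0.001, the DNA methylation machinery, lay below it. Germline genes (2 measured, median 0.03) and sex-linked genes (4 measured, median 0.01, mean -0.01) were too few to test.

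Every list p-value treats the members of a list as nearly independent genes. A correlation between members cannot be estimated without values per library. The counts adjusted over the list alone carry no correction over the 41 lists. Their genes come from the same 14 mice and are not independent results. The authors' deposited table held 32 of 42 interferon, 28 of 54 chemokine, 16 of 24 reactive astrocyte and 13 of 21 complement genes. An unknown filter can keep a weak gene only where it was higher. The counts of higher members in these lists may therefore be too high.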

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

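All alternatives to the list test reported here were chosen after the results were seen, while those of the gene counts were planned. At an adjusted threshold of 0.1 the authors' deposited table still held 0 genes, and with a mean of at least 1 CPM (12697 genes) 0 passed, with a smallest adjusted p of 0.782 and 557 higher and 57 lower at an unadjusted p under 0.05. Of the 20 called lists, 10 kept direction and call under every alternative that could be run, all 7 except for MHC class II (6), which had too few members once shared ones were left out, as did the uncalled D1-type list: 8 higher (interferon, MHC class I, MHC class II, activated microglia, microglia, chemokine, leukocyte, reactive astrocyte) and 2 lower (synaptic vesicle, channel). The number of lists called lower went from 8 to 5 at a correlation of 0.05, 2 at 0.1 and 3 with the fold change as statistic. Adjusted p at a correlation of 0.05 was 0.0904 for interneuron, 0.0536 for choroid plexus, 0.134 for GABA and 0.154 for postsynaptic lists. At 0.1 it was 0.195, 0.106, 0.251 and 0.324 for those 4, 0.0918 for cortical, 0.124 for glutamate receptor and 0.152 for protocadherin lists. A higher assumed correlation widens the test's error by construction. A separate scan, not counted among the 7 alternatives, raised the preset further. Of the 10 kept lists, the call held up to 0.16 for channel, 0.23 for vesicle, 0.27 for microglia, 0.3 for chemokine, 0.41 for leukocyte and 0.44 for reactive astrocyte lists. For activated microglia, MHC class I, interferon and MHC class II lists it held up to 0.61, 0.72, 0.82 and 0.83. With the fold change as statistic the adjusted p was 0.0530 for interneuron, 0.1005 for endothelial, 0.107 for glutamate receptor, 0.295 for GABA, 0.193 for protocadherin, 0.370 for postsynaptic and 0.0746 for ribosomal protein lists. With the length trend removed it was 0.0815 for glutamate receptor, 0.0935 for GABA and 0.278 for postsynaptic lists. Leaving out shared members gave 0.0726 for interneuron and 0.372 for complement lists, and a mean of at least 1 CPM gave 0.0513 for choroid plexus. Uncalled lists that changed sign were D2-type markers (0.857 with the fold change as statistic, 0.954 without shared members, 0.917 with the length trend removed), oligodendrocyte (0.885 with ranks, 0.982 with the fold change), oligodendrocyte precursor (0.988 with the length trend removed) and extracellular matrix (0.848 with the fold change). Lists not called in the main test passed for activity-regulated (0.0263 with ranks, 0.0103 with the length trend removed), respiratory chain (0.0263 and 0.000710, lower), mural and fibroblast (0.0230 with ranks) and glucocorticoid-responsive genes (0.0483 with the length trend removed). Apart from the correlation, the cause was not tested. Not run, for want of values per library, were the count-based test and quality weights, other normalizations, no filter, pseudocounts, a block for the animal number series, a surrogate variable, each library left out, an estimated correlation, fry, marker levels per library, the permutation test of Tet1 and other splits of the mice. No paired analysis was possible because the replicate numbers are names only and no library values were used here. Whether 1 mouse or a few decide a list, and what depth limits, therefore stays unknown.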

Other observations

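Immunoglobulin genes, a group chosen after their values were seen, were higher in AAV-Cre in all 56 members that the authors' deposited table holds. Their median log2 fold change was 3.05, and 45 had an unadjusted p under 0.05. The heavy chain constant gene Ighg1 stood at 6.85 ± 1.68 (standard error) and Ighm at 1.76 ± 0.71 in the authors' deposited table, beside Igkc at 2.92 ± 1.03. Of the 56 genes, 42 had a mean under 1 CPM, where a fitted fold change depends on offsets that are not known here, and related segments can share reads. The authors' low-gene filter is not known either, and a filter that keeps a weak gene when it is high in 1 group would leave out segments that were not higher, so the count of 56 is no test of direction. With a mean of at least 1 CPM there were 14 such genes, all higher, with a median of 3.39. That cut is on the mean over both groups, so a gene can pass it through AAV-Cre alone. This count is therefore no test of direction either. All 7 measured guanylate-binding protein (Gbp) genes had an unadjusted p under 0.05, as did 2 of 4 Gimap and 2 of 2 Slfn genes, families of lymphocyte and interferon biology also picked after their values were seen. A pool of 9 immune and glial reaction lists, joined after their medians were seen, held 42 of the 100 genes of smallest p, where 1.12 would fall by chance if genes were independent.

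Of the explanations tested below, those on weakly expressed genes, on spread between mice, on the length trend in the vesicle and channel lists, on short messages and on projection neuron, interneuron and cortical share were chosen after the result, or members that reveal it, had been seen. The remaining tests were written down once the immune genes at the top of the table had been seen but before the list values they measure were. Those top genes included H2-Eb1, H2-Ab1, H2-Aa and Cd74, which belong to the activated microglia list. The neuron share test, which uses that list, was therefore not blind to its result. Of the 12 tests, 4 (neuron share, weakly expressed genes, the length trend in ribosomal protein genes, short messages) were set aside after list values were known and then put back, so that all are given. In the blood test, the bootstrap interval and the repeat without weak genes were added after its values were seen. Other splits of the mice could not be tried without library values. Every bootstrap interval below resamples the genes of a list. It leaves out each gene's own standard error and does not measure spread between mice.

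The first pattern is the joint rise of interferon, MHC and leukocyte lists. More blood in the AAV-Cre tissue would raise red cell genes at least as much as leukocyte genes, but their median was -0.0225 against 1.53, with upper 95% limits of the 5 genes between 0.84 and 0.92 and a bootstrap interval of the difference of 0.42 to 2.27. Only 8 of 29 leukocyte genes and 5 of 10 red cell genes were in the table. An unknown filter can leave weak leukocyte genes in only where they were higher, which limits this test and the meningeal one. Over the 6 leukocyte genes with a mean over both groups of at least 1 CPM, the median was 1.13 and the difference 1.16 (0.19 to 2.59). That cut, too, can keep a gene through AAV-Cre alone. A lower share of neurons alone would raise other cell types alike, yet the activated microglia median lay 0.60 above the oligodendrocyte median (0.38 to 1.15) and 0.47 above the endothelial one (0.23 to 1.03). The activated microglia list holds H2-Eb1, H2-Ab1, H2-Aa and Cd74 of the MHC class II list, so its excess partly restates the pattern. Microglia markers had a median of 0.35, against 0.05 for oligodendrocyte and 0.18 for endothelial markers, differences that were not tested. The medians were thus not alike, which argues against neuron share as the whole cause only to that extent, and not against a part in it. The MHC class I median of 0.76 lay above level-matched lists (-0.02 to 0.07). All 22 of its genes had a mean of at least 1 CPM, so it cannot test noise of weakly expressed genes in the leukocyte list, where 6 of 8 did. More meningeal or choroid plexus tissue stays open: the leukocyte median lay 1.40 above the mural and fibroblast median (0.27 to 2.14), but the 1.16 above the choroid plexus median had an interval of -0.09 to 1.90. Loss of Tet1 cannot be told apart from an effect of Cre or of the virus preparation, since 0 libraries had Cre with intact Tet1 alleles.

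The second pattern is that fold changes this large came with no gene past the adjusted threshold. The median standard error of the 67 interferon, MHC and leukocyte genes was 0.273, against 0.105 for genes at the same level (95% of matched lists 0.091 to 0.123), or 2.60 times as large. The standard error was derived as the fold change divided by t. Large fold changes with no gene past the threshold therefore require large standard errors. The comparison restates the pattern and is no separate test of its cause. A larger standard error was not particular to immune genes: 32 of 41 lists lay above the 95% range of their matched lists, among them red blood cell (4.66 times), cortical (4.23 times), activity-regulated (2.33 times) and oligodendrocyte genes (1.86 times). The values show wide spread in the immune genes, and whether it comes from the immune change itself, from tissue composition or from a few mice stays open without values per library.

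The third pattern is higher ribosomal protein genes with lower vesicle and channel genes. A trend of t with exonic length (rho of -0.26 across genes, which are not independent replicates) is not the whole cause. With that trend removed the ribosomal list kept a p of 2.08e-09 in limma's camera test. The vesicle and channel lists kept adjusted p of 3.35e-08 and 6.06e-06. Exonic length here joins all annotated exons of a gene and can exceed the length of the transcripts present. An effect of transcript length itself therefore stays open. Genes of shorter exonic length did have higher t, but shortness alone would raise the respiratory chain genes as much. These were also short by that measure (median exonic length 2147 bases, against 1830 for ribosomal protein and 4368 for all genes). The ribosomal median lay 0.16 above theirs, with an interval over genes, not mice, of 0.15 to 0.18. A lower share of striatal projection neurons is argued against by their median, 0.21 above the vesicle median (0.16 to 0.26 over genes), though without a test between mice. A lower share of interneurons stays open, their median being 0.083 above the vesicle median (-0.016 to 0.15). A lower share of cortical neurons in the AAV-Cre punches remains a possible explanation: the cortical list was lower in limma's camera test, with a p of 0.00235 before adjustment (adjusted p = 0.00573), and its median differed from the vesicle median by -0.29 (-0.54 to 0.06). That criterion was set when the value was already known and 0 cortical genes had an unadjusted p under 0.05, so it carries little weight, and a biological loss of release and channel transcripts was not tested apart from it.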
